A study of Mus musculus with 17 samples.

How the data were processed

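The data are RNA-seq gene counts from mouse lacrimal gland tissue and lacrimal gland organoids, in one table of 9 libraries (tissue, uncloned organoids in EM and DM) and another of 8 libraries (WT and labelled Pax6-KO clones in EM and DM). Per the labels' protocols, RNA came from organoids retrieved from basement membrane extract and libraries were made with a stranded polyadenylated RNA kit. Per the submitters' processing notes, reads were aligned to GRCm38 with STAR and the deposited counts per gene were made with featureCounts. Versions and settings are not given in the sources used here. The deposited counts are whole numbers, not normalised. The bulk table holds 38293 gene IDs, of which 36429 matched GENCODE M21, with 0.313% of counts on the others, and 16493 had no counts. The clone table holds 55487 gene IDs, of which 55227 matched, with 0.00821% of counts on the others, and 27383 had no counts. The ID sets differ, with 36142 in both tables, so each table was fitted alone. The annotation releases used to count them are not given either.

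Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, leaving 13713 genes in the bulk table and 14282 in the clone table. Library sizes were scaled by the trimmed mean of M-values, and CPM use the scaled library sizes. Each table was fitted with a mean per group by the quasi-likelihood method, with 6 residual degrees of freedom in the bulk table and 4 in the clone table and a biological coefficient of variation of 0.138 and 0.234. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. The SE is the absolute log2 fold change divided by the square root of the test's F. Bounds for a group at 0 rest on 3 counts over the group. Intervals for a group with 1 to 3 counts are exact 95% Poisson intervals. Both cover counting error only. Total counts ran from 12801473 to 19207469 in the bulk table and from 18282059 to 22500534 in the clone table.

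The comparisons were uncloned EM and DM with tissue, DM with EM in uncloned organoids, WT clones and labelled KO clones, labelled KO with WT in each medium, and the interaction of both. Named genes were chosen by a rule: Pax6 first, then the 6 largest rises and 6 largest falls among called genes whose groups do not overlap and whose mean is at least 10 CPM in a group, without predicted or unnamed genes. To these were added up to 4 members with the smallest p of each list described. Some of these members are not reported here. For the interaction the groups could overlap. No gene was called there by edgeR without a block, so the rule was applied to the fit with the clone as a block, a choice made after seeing that count. Gene lists, written from textbook knowledge, covered tear proteins, acinar machinery, duct and ion transport, basal and myoepithelial cells, cell cycle, Notch, Wnt, growth factor, BMP and TGF-beta targets, transcription regulators of lacrimal gland and eye, keratinization, cornea and conjunctiva, retinoids, cholesterol, interferon, p53, stress and hypoxia. They also covered other cell types: lymphocytes, macrophages, endothelium, fibroblasts, nerve, fat and muscle, salivary gland, and sex-linked transcripts. Lists of at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a comparison. The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined, except total-count scaling, which was added after seeing the data. Which lists are described beside which comparison was also chosen after seeing the data.

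The alternatives were DESeq2's size factors, DESeq2 1.42.0 itself, no filter on low counts, only the libraries of both groups compared, each library left out in turn, a block on line or clone, and total-count scaling. Similarity was also computed with Pearson's r and over genes of at least 10 CPM, and agreement between the tables with labelled KO in place of WT clones. The block rests on the labels, which give the same line in EM, DM and tissue and the same clone in EM and DM. As a check, deviations from the group means correlated at 0.18, 0.12 and 0.09 between EM and DM of lines 6, 7 and 8, and between -0.07 and 0.08 between tissue and organoids of a line. They correlated at 0.60 (WT) and 0.51 (labelled KO) between EM and DM of a clone. With 2 clones per label their deviations mirror each other, so each of these is a single value. Similarity to the gland was tested with an exact two-sided permutation test, and the share of genes moving toward the gland was set beside 100 simulations of unchanged groups.

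No library was left out of the comparisons, and all columns of values in both tables were used. Reads and exon-level counts were not analysed here.

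The steps were tested on simulated data, counts with 100 genes changed 2-fold and 100 changed 4-fold. For uncloned DM against EM (13713 genes), 88% of the 100 genes changed 2-fold and 100% of those changed 4-fold were recovered, and 6.93% of calls were on unchanged genes. For EM against tissue, 74% at 2-fold and 97% at 4-fold were recovered, with 3.93% of calls on unchanged genes. For DM against tissue, the shares were 71% at 2-fold, 97% at 4-fold and 5.62%. For WT DM against EM (14282 genes) they were 37% at 2-fold, 69% at 4-fold and 4.50%. For KO DM against EM they were 41% at 2-fold, 84% at 4-fold and 8.09%. For KO against WT in EM they were 34% at 2-fold, 79% at 4-fold and 8.13%. For KO against WT in DM they were 29% at 2-fold, 82% at 4-fold and 6.72%. For the interaction they were 10% at 2-fold, 70% at 4-fold and 14.0%.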

Results

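Polyadenylated RNA was sequenced from mouse lacrimal gland, which secretes the aqueous part of tears, and from its organoids, epithelial cultures grown in basement membrane extract. The 17 libraries form 7 groups. Gland tissue, uncloned (bulk) organoids in expansion medium (EM) and uncloned organoids in differentiation medium (DM) have 3 samples each, numbered as lines 6, 7 and 8. The other groups are 2 wild-type (WT) clones and 2 clones labelled Pax6-KO, each grown in EM and in DM. Per the growth protocol, EM cultures spent 7 days in EM, and DM cultures spent 2 days in EM followed by 5 in DM. The series text instead gives 7 days of exposure to each medium for the clones, so their time in DM is uncertain. Total counts ran from 14144109 to 19207469 in the gland, from 14674166 to 16542195 in uncloned EM and from 12801473 to 16751502 in uncloned DM. They ran from 18282059 to 22500534 in WT and from 18965633 to 19454717 in labelled KO clones. Values in parentheses are log2 fold changes ± SE with adjusted p from edgeR. For a gene with no counts in a group, a bound from 3 counts over that group is given, and with 1 to 3 counts a ratio with its interval. Gene lists were tested with camera, which compares a list with other genes, and the adjusted p of fry, which does not, follows where it falls on the other side of 0.05. Numbers given by list are calls adjusted over that list alone, where these differ. Positions are on GRCm38. The largest rises and falls are the 6 at each end under the naming rule.

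Pax6, a transcription factor that directs eye development and the target of the labelled knockout, was read first in every library (ENSMUSG00000027168, chromosome 2, 105668900 to 105697364). It stood at 302 ± 9.66 CPM (SD, n = 3) in the gland, 173 ± 23.7 CPM (n = 3) in uncloned EM and 177 ± 9.05 CPM (n = 3) in uncloned DM. Tissue and uncloned libraries were scaled apart from the clones, so levels are compared only within each table. WT clones had 245 and 276 CPM in EM and 219 and 280 CPM in DM. Clones labelled Pax6-KO had 172 and 272 CPM in EM and 135 and 309 CPM in DM. Labelled KO and WT did not differ past the test in EM (-0.23 ± 0.39, adjusted p = 0.744) or in DM (-0.17 ± 0.39, adjusted p = 0.831), so the transcript level gives no check of the labels, from which every direction below is drawn. A count over the whole gene does not test for a short sequence change within it. Against the gland, Pax6 was lower in EM (-0.80 ± 0.10, adjusted p = 2.32e-05) and in DM (-0.77 ± 0.10, adjusted p = 3.21e-05) with trimmed-mean scaling and higher in both with total-count scaling, at 1.26 and 1.21.

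**Figure D1:**
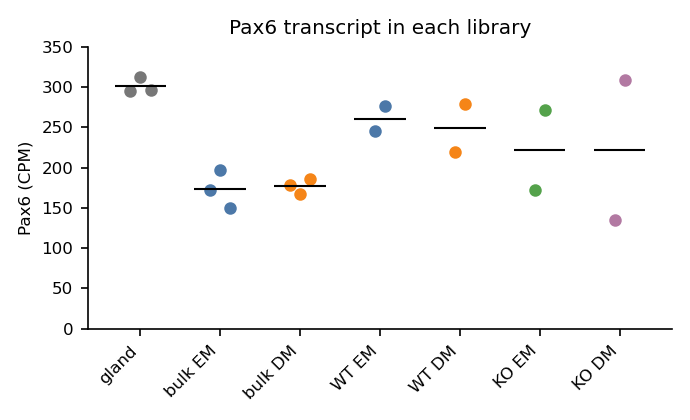
Pax6 transcript level in CPM (y axis, linear) for each of the 17 libraries, by group (x axis); points are libraries and lines are group means. The libraries labelled Pax6-KO lie between 135 and 309 CPM and overlap the WT libraries, which lie between 219 and 280 CPM.

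Uncloned EM was compared with the gland to show which transcripts an expanding culture carries. Most secreted tear proteins stood far below the gland, while basal cell keratins, glycolytic enzymes and cell division genes stood above it. Among 28 tear proteins and lacrimal secretory products, 23 fell and 4 rose. The tear protein list gave camera adjusted p = 1.31e-37 and adjusted p = 7.25e-04 with an estimated correlation. Car6, a secreted carbonic anhydrase, stood at 5124 ± 334 CPM in the gland and 0.0675 ± 0.0495 CPM in EM (n = 3 each, -16.10 ± 0.23, adjusted p = 1.14e-11). Lpo, the peroxidase of tears and saliva, stood at 4259 ± 886 and 0.623 ± 0.148 CPM (-12.73 ± 0.27, adjusted p = 3.16e-11). The mucosal glycoprotein Dmbt1 was 106010.0-fold lower, 95% interval 19027 to 4187100.0, and the secretoglobin Scgb2b7 was 1150400.0-fold lower, 95% interval 318460.0 to 9499100.0 (adjusted p at most 1.99e-11). The largest falls were in the secretoglobins Scgb2b24 (-20.35 ± 0.58) and Scgb1b20 (at least 940950.0-fold lower), and in the odorant-binding proteins Obp1a (-20.42 ± 0.63) and Obp1b (-21.07 ± 0.55). The mucin-like Mucl2 (-20.52 ± 0.96) and the secreted nuclease Dnase1 (at least 248460.0-fold lower) completed them (adjusted p at most 6.39e-09). Secretoglobins and odorant-binding proteins are families of close copies, so the value of any single member is uncertain.

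Acinar secretory genes were lower for 20 of 26 and higher for 5, at camera adjusted p = 3.54e-09 and adjusted p = 0.0250 with an estimated correlation, but 12 were higher and 11 lower with total-count scaling. Bhlha15, a transcription factor of mature secretory cells, stood at 1123 ± 41.8 CPM in the gland and 1.11 ± 0.0513 CPM in EM (-9.97 ± 0.19, adjusted p = 2.42e-11). The apical water channel Aqp5 (-7.44 ± 0.15), the transcription factor Creb3l1 (-7.27 ± 0.22) and the translocon subunit Sec61b (-2.60 ± 0.09) fell (adjusted p at most 5.01e-10).

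Basal cell genes rose for 17 of 18 and fell for none. The basal cell list gave camera adjusted p = 3.65e-16 and adjusted p = 0.0250 with an estimated correlation. Krt5, a basal keratin, stood at 29.3 ± 5.89 CPM in the gland and 1863 ± 115 CPM in EM (5.98 ± 0.17, adjusted p = 1.75e-10). Krt17 (7.37 ± 0.17) and the hemidesmosome collagen Col17a1 (3.99 ± 0.13) rose too (adjusted p at most 3.59e-10). All 20 tested genes of hypoxia and glycolysis rose. The glycolysis list gave camera adjusted p = 4.45e-23 and adjusted p = 0.0215 with an estimated correlation. They included the glycolytic enzymes Eno1 (4.04 ± 0.09), Gapdh (4.47 ± 0.11), Pgk1 (3.80 ± 0.09) and Pfkp (5.52 ± 0.16; adjusted p at most 1.91e-10). Cholesterol biosynthesis genes rose for 23 of 24 and fell for 1. The cholesterol list gave camera adjusted p = 1.34e-14 and adjusted p = 0.0451 with an estimated correlation. The sterol enzyme Nsdhl (3.29 ± 0.10) and the sterol carrier Stard4 (4.78 ± 0.15) were among them (adjusted p at most 3.84e-10).

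Cell cycle genes rose for 28 of 30 and fell for none. The cell cycle list gave camera adjusted p = 2.52e-04 and adjusted p = 0.501 with an estimated correlation. The cyclin Ccnd1 (2.01 ± 0.14), the chromatin protein Hmgb2 (2.72 ± 0.24) and the centromere protein Cenpf (4.38 ± 0.46) rose (adjusted p at most 5.16e-06). Ube2c, a ubiquitin conjugase of mitosis, stood at 4.55 ± 2.12 and 75.4 ± 4.89 CPM (adjusted p = 1.43e-06). Interferon response genes rose for 22 of 23 and fell for 1 (22 up and 0 down with total-count scaling), at camera adjusted p = 2.90e-05 and adjusted p = 0.378 with an estimated correlation. They included Oasl2 (4.51 ± 0.29), Ifit1 (4.07 ± 0.29), Ifi44 (4.70 ± 0.34) and Isg15 (4.95 ± 0.37; adjusted p at most 2.80e-07).

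Fibroblast genes fell for 14 of 16 and rose for 2, at camera adjusted p = 5.32e-15 and adjusted p = 0.0157 with an estimated correlation. The matrix proteins Dcn (-11.09 ± 0.32), Sparc (-7.35 ± 0.24), Col1a1 (1892-fold lower, 95% interval 648 to 9177) and Col6a1 (798-fold lower, 95% interval 273 to 3870.4) fell (adjusted p at most 2.17e-09). Macrophage and dendritic cell genes fell for 16 of 17 and rose for 1, at camera adjusted p = 1.50e-11 and adjusted p = 0.0830 with an estimated correlation. The rise did not pass without gland 6, gland 8, EM of line 6 or EM of line 7. The antigen presentation genes H2-Aa (at least 3647-fold lower), Cd74 (-7.38 ± 0.28) and H2-Ab1 (-4.09 ± 0.17) and the receptor Csf1r (-8.24 ± 0.35) fell (adjusted p at most 2.82e-09). Endothelial and pericyte genes fell for 13 of 14 and rose for 1, at camera adjusted p = 7.37e-05 and adjusted p = 0.0259 with an estimated correlation. Vwf (-4.66 ± 0.28), Pecam1 (428-fold lower, 95% interval 118 to 3532) and Rgs5 (-5.63 ± 0.42) fell, and the receptor Notch3 rose (3.79 ± 0.19; adjusted p at most 2.86e-07).

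The largest rises, all from no counts in the gland, were the inducible nitric oxide synthase Nos2 (at least 436-fold higher; ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), Mab21l3 (at least 208-fold higher) and the granulocyte growth factor Csf3 (at least 152-fold higher). Olfm5 (at least 150.5-fold higher), Clca3b (at least 133-fold higher) and the protease Htra4 (at least 81.8-fold higher) followed (adjusted p at most 1.03e-04). Of 13713 tested genes 10259 differed, 5130 up and 5129 down, and 6316 of them by a log2 fold change of at least 1 in size. The 10 most abundant genes held 65.5 to 67.6% of the gland's counts and 5.93 to 7.36% of the organoids'. With total-count scaling, chosen after seeing the data, the median of all genes moved by 2.06 (log2), and 11493 genes were up and 1302 down.

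Uncloned DM was compared with uncloned EM to show what differed after 5 days of DM in cultures of the same total length. Most contractile genes of myoepithelial cells, BMP and TGF-beta targets and genes of stratified epithelium rose, and most Wnt targets fell. Some markers of fibroblasts and the pericyte marker Rgs5 rose with them. Myoepithelial genes rose for 8 of 10 and fell for none, at camera adjusted p = 1.23e-12 and adjusted p = 0.0505 with an estimated correlation. Mylk, the kinase that activates smooth muscle myosin, went from 0.548 ± 0.179 to 47.7 ± 12.3 CPM (n = 3 each, 6.41 ± 0.28, adjusted p = 4.88e-07). Smooth muscle actin Acta2 went from 5.74 ± 0.465 to 118 ± 59.3 CPM (4.36 ± 0.30, adjusted p = 6.39e-06), and Actg2 (4.28 ± 0.35) and Tagln (4.27 ± 0.39) rose with it (adjusted p at most 2.62e-05). BMP and TGF-beta targets rose for 11 of 13 (12 up, 0 down by list), at camera adjusted p = 3.00e-13 and adjusted p = 0.0505 with an estimated correlation. The matrix protein Tgfbi (2.99 ± 0.20), the feedback inhibitor Pmepa1 (4.41 ± 0.32) and Ccn2 (1.91 ± 0.17) rose (adjusted p at most 2.59e-05). Fibroblast genes rose for 5 of 16 and fell for 1 (6 up, 1 down by list), and 6 had no counts in either medium. The fibroblast list gave camera adjusted p = 0.0169 and adjusted p = 0.474 with an estimated correlation, and adjusted p = 0.272 with the line as a block. The matrix proteins Sparc, from 0.909 ± 0.432 to 22.0 ± 2.86 CPM (4.57 ± 0.23, adjusted p = 1.23e-06), and Fn1 (1.90 ± 0.18, adjusted p = 3.36e-05) rose, as did Thy1 (at least 12.6-fold higher, adjusted p = 0.00397). Fbln1 fell (-0.85 ± 0.22, adjusted p = 0.0124) but did not pass without DM of line 6 (adjusted p = 0.0553). Endothelial and pericyte genes rose for 3 of 14 and fell for 1. That list gave camera adjusted p = 0.457 and adjusted p = 0.640 with an estimated correlation, and adjusted p = 0.00327 with fry. The pericyte marker Rgs5 rose (6.90 ± 0.39, adjusted p = 2.40e-06), and Vwf fell (-1.61 ± 0.38, adjusted p = 0.00839). Abcc9 (2.43 ± 0.69) and Pecam1 (7.05-fold higher, 95% interval 1.95 to 58.2), both under 1 CPM in EM and DM, rose (adjusted p at most 0.0348), but Abcc9 did not pass without EM of line 6 or 8 or DM of line 6 or 7, nor Pecam1 without any organoid library except DM of line 6 (adjusted p up to 0.101). Macrophage genes rose for 3 of 17 and fell for 1, at camera adjusted p = 0.655 and adjusted p = 0.866 with an estimated correlation. They were Cd74 (2.56 ± 0.31), H2-Aa (at least 15.2-fold higher, from no counts to 0.603 CPM) and Csf1r (1.98 ± 0.52), which rose, and H2-Ab1 (-0.74 ± 0.19), which fell (adjusted p at most 0.0155). Csf1r did not pass without EM of line 7 or 8 or DM of line 6 (adjusted p up to 0.0600). Of 6 nerve genes Ncmap rose (2.08 ± 0.32, adjusted p = 0.00143), and that list gave camera adjusted p = 0.641 and adjusted p = 0.775 with an estimated correlation, and adjusted p = 0.00226 with fry. Without DM of line 8 another nerve gene fell.

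Wnt targets fell for 8 of 11 and rose for 2, at camera adjusted p = 3.01e-05 and adjusted p = 0.0505 with an estimated correlation. Axin2, a feedback inhibitor of Wnt signalling, fell from 23.2 ± 1.54 to 2.70 ± 0.392 CPM (-3.10 ± 0.18, adjusted p = 2.51e-06; ENSMUSG00000000142, chromosome 11, 108920349 to 108950783). The receptor Tnfrsf19 (-2.58 ± 0.26) and the Wnt deacylase Notum (-3.00 ± 0.41) fell, and the pathway inhibitor Nkd2 rose (3.77 ± 0.44; adjusted p at most 3.65e-04).

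Keratinization genes rose for 13 of 18 and fell for 2, at camera adjusted p = 1.41e-05 and adjusted p = 0.0505 with an estimated correlation. The falls numbered at most 1 with any 1 organoid library other than DM of line 8 left out. The rises included the desmosomal cadherin Dsg3 (2.46 ± 0.17), Krt6a (1.75 ± 0.19) and the envelope proteins Sprr2d (2.90 ± 0.31, one of several close copies) and Sprr1a (1.28 ± 0.15; adjusted p at most 1.45e-04). Basal cell genes rose for 9 of 18 and fell for 3, at camera adjusted p = 0.00214 and adjusted p = 0.474 with an estimated correlation. Only 1 fell without EM of line 7, DM of line 6 or DM of line 7. Krt14 (1.64 ± 0.15), the caveolar protein Cav1 (1.32 ± 0.14) and Col17a1 (0.96 ± 0.10) rose (adjusted p at most 8.11e-05). Acinar secretory genes rose for 10 of 26 and fell for 1 (10 up, 2 down by list). The acinar list gave camera adjusted p = 0.00440 and adjusted p = 0.211 with an estimated correlation, and 5 fell without DM of line 8. Aqp5 rose from 1.92 ± 0.280 to 22.1 ± 2.10 CPM (3.53 ± 0.14, adjusted p = 4.88e-07), against 334 ± 33.5 CPM in the gland. The granule regulator Rab27b (1.73 ± 0.15), the calcium release channel Itpr3 (0.92 ± 0.11) and the potassium channel Kcnn4 (3.00 ± 0.38) rose (adjusted p at most 2.27e-04).

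Tear proteins rose for 7 of 28 and fell for 3, at camera adjusted p = 0.555 and adjusted p = 0.775 with an estimated correlation. The rises were 4, 4 and 3 without EM of line 6, 7 and 8, and 1 fell without EM of line 6, DM of line 6 or DM of line 7. Wfdc2 fell (-1.05 ± 0.16) and Wfdc18 rose (1.03 ± 0.20), both of the whey acidic protein family (adjusted p at most 0.00297). Lpo (1.30 ± 0.30) and Dmbt1 (14.4-fold higher, 95% interval 2.58 to 568) rose, to 1.53 ± 0.296 and 0.190 ± 0.0761 CPM (adjusted p at most 0.00826). Retinoid genes rose for 7 of 17 and fell for 3, at camera adjusted p = 0.0291 and adjusted p = 0.237 with an estimated correlation and adjusted p = 0.223 with the line as a block, and 5 fell without DM of line 8. The retinoic acid binding protein Crabp2 (2.21 ± 0.19), the retinol dehydrogenase Rdh10 (2.55 ± 0.29) and the retinoic acid hydroxylase Cyp26b1 (2.49 ± 0.32) rose (adjusted p at most 2.33e-04). Aldh1a3, which makes retinoic acid, went from 42.4 ± 1.65 to 959 ± 562 CPM (adjusted p = 4.01e-05). Duct and ion transport genes split into 6 up and 6 down of 17 (5 up and 6 down with total-count scaling). The duct list gave camera adjusted p = 0.976 and adjusted p = 0.979 with an estimated correlation. Krt8 (1.02 ± 0.10), Krt18 (0.83 ± 0.10), the water channel Aqp4 (2.84 ± 0.33) and the carbonic anhydrase Car2 (1.86 ± 0.22) rose (adjusted p at most 1.44e-04). Cholesterol biosynthesis genes fell for 9 of 24 and rose for 2 (3 up, 11 down by list), at camera adjusted p = 0.00570 and adjusted p = 0.640 with an estimated correlation. Only 1 rose without EM of line 6, EM of line 7 or DM of line 6. The sterol enzymes Dhcr7 (-1.35 ± 0.14) and Lss (-0.79 ± 0.10), and also Insig1 (-0.74 ± 0.13) fell (adjusted p at most 0.00133).

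Cell cycle genes fell for 2 of 30 and rose for none (0 up, 1 down by list; 10 fell with the line as a block), at camera adjusted p = 0.00570 and adjusted p = 0.775 with an estimated correlation, and adjusted p = 0.245 with fry. This count rests on DM of line 8, since 28 of 30 fell without that library and 1 or 2 without any other organoid library. With all libraries the falls were Hmgb2 (-1.01 ± 0.22) and the transcription factor E2f1 (-0.78 ± 0.26; adjusted p at most 0.0406). E2f1 did not pass without EM of line 6 or 8 or DM of line 6 or 7, at adjusted p of 0.083 to 0.156. The median of this list in DM (log2 CPM from each gene's mean) was 0.04, 0.33 and 1.22 in lines 6, 7 and 8, against 1.15 to 1.31 in EM. For the genes that DM raised, line 8 also lay nearer to EM than the other DM lines. The largest rises were the metalloprotease Adam12 (at least 309.7-fold higher; ENSMUSG00000054555, chromosome 7, 133883199 to 134232146), the decoy receptor Tnfrsf11b (665-fold higher, 95% interval 228 to 3226) and the growth factor Csf2 (682-fold higher, 95% interval 189 to 5632). The interleukin 33 receptor Il1rl1 (7.99 ± 0.71), the matrix protein Postn (7.92 ± 0.52) and Acsbg1 (7.14 ± 0.83) followed (adjusted p at most 3.14e-04). The largest falls besides Axin2 were the tight junction protein Cldn8 (-3.18 ± 0.30), Pigz (-3.18 ± 0.26), the transporter Slc16a6 (-3.50 ± 0.30), Olfm5 (-3.55 ± 0.56) and Lgi2 (-3.73 ± 0.26; adjusted p at most 0.00150). Of 13713 tested genes 4158 changed, 2352 up and 1806 down (1952 up and 2597 down with total-count scaling), and 1492 of them by a log2 fold change of at least 1 in size. The falls were 1039, 1151, 1170 and 1185 without DM of line 6, DM of line 7, EM of line 8 and EM of line 7, and 2581 without DM of line 8.

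**Figure D2:**
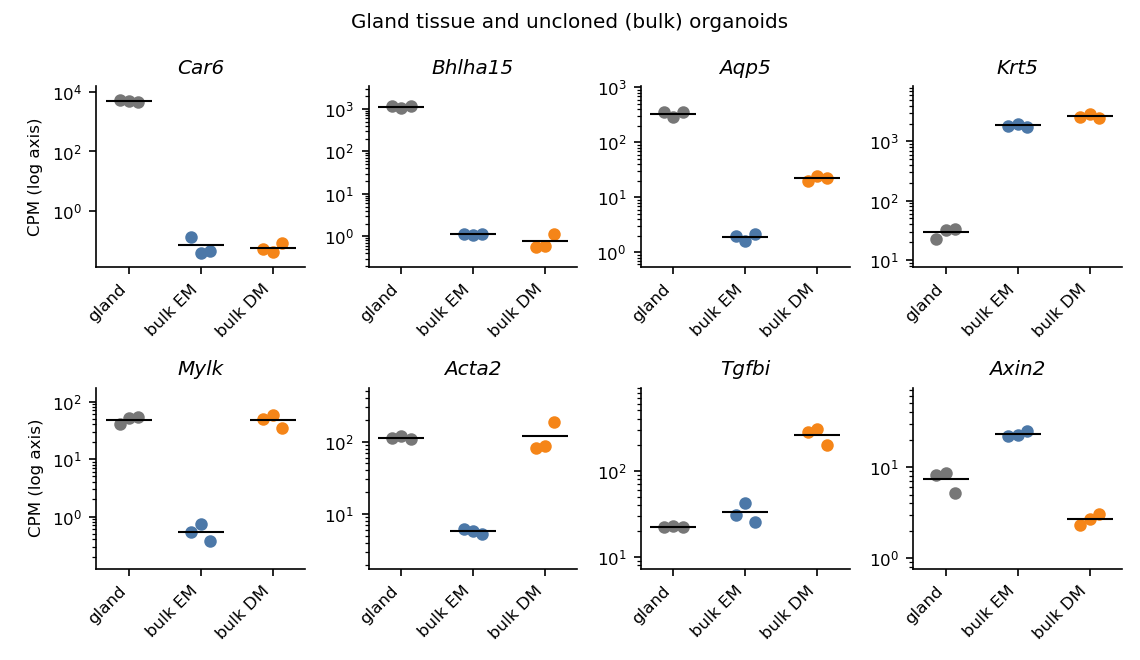
Level in CPM (y axis, log scale with its own range per gene) of 8 genes in gland tissue and uncloned (bulk) organoids in EM and DM (x axis); points are libraries and lines are means. Car6 and Bhlha15 are lower and Krt5 higher in both organoid groups than in the gland, and Aqp5, Mylk, Acta2 and Tgfbi are higher and Axin2 lower in DM than in EM.

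Uncloned DM was compared with the gland to show what separated the cultures from it. Tear proteins stood below the gland for 23 of 28 and above it for 5, at camera adjusted p = 1.59e-35 and adjusted p = 0.00322 with an estimated correlation. Car6 (-16.30 ± 0.24), Dmbt1 (-12.74 ± 0.23), the exocrine peptide Esp6 (-14.68 ± 0.32) and Scgb2b7 (1076800.0-fold lower, 95% interval 298080.0 to 8891200.0) were lower (adjusted p at most 3.82e-11), Esp6 and Scgb2b7 being members of families of close copies. Acinar secretory genes were lower for 18 of 26 and higher for 6, at camera adjusted p = 1.69e-06 and adjusted p = 0.0494 with an estimated correlation, but 14 were higher and 11 lower with total-count scaling. Bhlha15 (-10.49 ± 0.20), Creb3l1 (-7.43 ± 0.23), Sec61b (-2.30 ± 0.09) and Aqp5 (-3.91 ± 0.12) were lower (adjusted p at most 9.72e-10). Myoepithelial genes were lower for 5 of 10 and higher for 2 (5 higher and 4 lower with total-count scaling), at camera adjusted p = 0.374 and adjusted p = 0.536 with an estimated correlation, and adjusted p = 2.09e-04 with fry. Smooth muscle myosin Myh11 (-8.90 ± 0.33) and calponin Cnn1 (-5.95 ± 0.48) were lower, and tropomyosin Tpm2 (2.90 ± 0.09) and smoothelin Smtn (2.60 ± 0.19) higher (adjusted p at most 5.43e-07). Keratinization genes were higher for 16 of 18 and lower for 1 (18 higher with total-count scaling), at camera adjusted p = 2.12e-07 and adjusted p = 0.0326 with an estimated correlation. Sprr1a (10.10 ± 0.29), Krt6a (9.45 ± 0.31), the desmosomal Pkp1 (7.52 ± 0.26) and Dsg3 (3540.4-fold higher, 95% interval 635 to 139840.0) were higher (adjusted p at most 6.22e-10). The largest rises, from no counts in the gland, were Mab21l3 (at least 285-fold higher), Psapl1 (at least 239.7-fold higher), the chemokine Ppbp (at least 191-fold higher), Nos2 (at least 182-fold higher), Lypd3 (at least 180.5-fold higher) and Htra4 (at least 164-fold higher; adjusted p at most 1.23e-04). The largest falls besides Scgb2b7 were Obp1a (-19.41 ± 0.61), Scgb1b2 (-19.58 ± 0.67), Sval2 (at least 170670.0-fold lower), Pnliprp1 (at least 183590.0-fold lower) and Dnase1 (at least 232560.0-fold lower; adjusted p at most 5.55e-09). Of 13713 tested genes 10358 differed, 5223 up and 5135 down, and with total-count scaling, where the median of all genes moved by 1.97, 11516 were up and 1270 down.

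Whether DM brought the cultures nearer to the gland was tested over 13713 genes. Spearman's rho across genes with the mean gland profile was 0.699 ± 0.00443 (SD, n = 3) in EM and 0.675 ± 0.00435 (n = 3) in DM. The difference of -0.0245 gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows. Of the 10259 genes that differed between EM and the gland, 54.3% moved toward the gland in DM, against 51.4 ± 0.65% (SD) in 100 simulations of unchanged groups sharing the EM libraries. The covariance of both sets of log2 fold changes was 0.368, against a simulated 0.0483 ± 0.0147. Genes lower in the gland that DM lowered numbered 899 (675.6 for independent lists), and genes higher in the gland that DM raised numbered 858 (879.7). DM also raised 994 genes lower in the gland (879.9) and lowered 542 genes higher in it (675.5). With total-count scaling 12795 genes differed and 61.2% of them moved toward the gland, against a simulated 49.8 ± 1.14%. DM then lowered 2387 genes lower in the gland (2176.6 for independent lists) and 105 higher in it (246.6), and raised 264 higher in it (185.3) and 1468 lower in it (1636). Among called genes, those that DM raised thus leaned away from the gland with trimmed-mean scaling and toward it with total-count scaling. Those that it lowered leaned toward it with both. Of all 5129 genes higher in the gland, called in DM or not, 53.2% rose with trimmed-mean scaling (simulated 50.1 ± 1.10%). The simulations leave DM unchanged, so an excess over them need not be a move toward the gland. The EM libraries serve both comparisons, as in the simulations, so the simulated values include what this sharing adds. Genes are not independent replicates, so no p is given across them.

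In the WT clones, DM was compared with EM to show the medium effect in single clones. Most BMP and TGF-beta targets and interferon response genes and part of the growth factor targets and contractile genes rose, and part of the Wnt targets and of the hypoxia genes fell. BMP and TGF-beta targets rose for 7 of 13 and fell for none (9 up, 0 down by list), at camera adjusted p = 1.48e-12 and adjusted p = 0.0381 with an estimated correlation. Pmepa1 rose from 12.4 ± 1.57 to 304 ± 74.0 CPM (n = 2 each, 4.61 ± 0.29, adjusted p = 8.64e-04). The signalling repressors Skil (2.08 ± 0.11) and Smad7 (2.66 ± 0.26) and Ccn2 (3.26 ± 0.41) rose (adjusted p at most 0.00471). Myoepithelial genes rose for 2 of 8 and fell for none (3 up, 0 down by list; 4 rose with the clone as a block), at camera adjusted p = 0.0107 and adjusted p = 0.302 with an estimated correlation. They were Smtn (1.44 ± 0.18) and Mylk (4.27 ± 0.73; adjusted p at most 0.0116). Mylk did not pass without EM clone 1 or EM clone 2. Of 5 tested fibroblast genes Fn1 rose (3.86 ± 0.45, adjusted p = 0.00381) and Fbln1 fell (-1.38 ± 0.35, adjusted p = 0.0417; 4 up, 1 down by list). Fbln1 did not pass with only the 4 libraries compared or without EM clone 1, EM clone 2 or DM clone 1. The list gave camera adjusted p = 0.0847 and adjusted p = 0.452 with an estimated correlation, and adjusted p = 0.0342 with fry, and 3 rose without DM clone 1. Of 5 endothelial and pericyte genes Rgs5 rose (5.65 ± 1.45, adjusted p = 0.0416), and of 5 macrophage genes Cd163 fell (at least 2.08-fold lower, adjusted p = 0.0400). Neither gene passed without any 1 of the 4 libraries, nor Cd163 with DESeq2 or with the clone as a block (adjusted p = 0.0608). Without DM clone 2 another endothelial gene fell. The endothelial and macrophage lists gave camera adjusted p = 0.463 and 0.936, and adjusted p = 0.649 and 0.938 with an estimated correlation. Acta1, skeletal actin, rose (5.64 ± 0.56, adjusted p = 0.00232) as 1 of 6 fat and muscle genes, at camera adjusted p = 0.385 and adjusted p = 0.649 with an estimated correlation. Of 2 lymphocyte genes, too few for camera, Pou2af1 fell (-3.66 ± 0.62, adjusted p = 0.0114). It did not pass without EM clone 1 or with only the 4 libraries compared. Mitochondrial transcripts held 1.67 and 1.77% of counts in WT EM and 1.06 and 1.11% in WT DM, and an rRNA-like transcript 1.94 and 1.74% against 1.40 and 1.23%. Wnt targets fell for 6 of 12 and rose for 1 (2 up, 7 down by list), at camera adjusted p = 0.00494 and adjusted p = 0.302 with an estimated correlation. Axin2 (-1.17 ± 0.12), the Wnt inhibitor Apcdd1 (-3.13 ± 0.49), Notum (-3.55 ± 0.67) and the receptor ligase Znrf3 (-0.59 ± 0.12) fell (adjusted p at most 0.0200). The Wnt falls were 2, 3 and 2 without EM clone 1, DM clone 1 and EM clone 2, and the rise did not pass without EM clone 1. Interferon response genes rose for 18 of 23 and fell for 1 (20 up, 1 down by list), at camera adjusted p = 7.66e-18 and adjusted p = 0.357 with an estimated correlation. Ifi44 (2.34 ± 0.19), the antiviral enzyme Rsad2 (3.03 ± 0.29), the RNA sensor Ddx58 (1.21 ± 0.16) and Ifit3 (2.46 ± 0.34) rose (adjusted p at most 0.00587). The interferon fall did not pass without EM clone 1, DM clone 1 or EM clone 2. The uncloned organoids did not show this rise. There DM raised 1 of 23 interferon response genes and lowered 0, at camera adjusted p = 0.555 and adjusted p = 0.866 with an estimated correlation. Growth factor and MAPK targets rose for 9 of 18 (11 up, 1 down by list). The growth factor list gave camera adjusted p = 0.00275 and adjusted p = 0.535 with an estimated correlation, and its rises were 1, 2 and 1 without EM clone 1, DM clone 1 and EM clone 2. The phosphatase Dusp4 (2.06 ± 0.24), the EGF receptor ligands Hbegf (1.06 ± 0.20) and Areg (1.25 ± 0.24) and the receptor Epha2 (0.86 ± 0.17) rose (adjusted p at most 0.0179). Cell cycle genes fell for 5 of 30 and rose for 1 (1 up, 6 down by list; 20 fell with the clone as a block), at camera adjusted p = 6.08e-06 and adjusted p = 0.649 with an estimated correlation, and adjusted p = 0.143 with fry. Hmgb2 (-1.41 ± 0.29), the replication helicase subunit Mcm2 (-0.72 ± 0.18) and Cdc20 (-1.62 ± 0.40) fell, and the cyclin Ccne1 rose (1.38 ± 0.29; adjusted p at most 0.0360). Without DM clone 1, 19 cell cycle genes fell, and without any other of the 4 libraries at most 2 did. Ccne1 did not pass without EM clone 1, EM clone 2 or DM clone 1, or with only the 4 libraries compared. Hypoxia and glycolysis genes fell for 2 of 20 and rose for none (0 up, 4 down by list; 7 fell with the clone as a block), at camera adjusted p = 0.00991 and adjusted p = 0.649 with an estimated correlation, and adjusted p = 0.105 with fry. They were Ndrg1 (-1.0017 ± 0.2222, adjusted p = 0.0265) and Gapdh (-0.59 ± 0.16, adjusted p = 0.0464). Neither passed without EM clone 1, DM clone 1 or EM clone 2. Gapdh also did not pass without DM clone 2, with only the 4 libraries compared or with DESeq2's size factors, and 2 others of the list fell without EM clone 2.

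In these clones the largest rises were Tnfrsf11b (at least 248-fold higher), Adam12 (at least 214-fold higher), Il1rl1 (1399-fold higher, 95% interval 479 to 6782) and the R-spondin receptor Lgr6 (8.53 ± 0.43; ENSMUSG00000042793, chromosome 1, 134983301 to 135105276). Postn (8.42 ± 1.90) and the ATP-gated channel P2rx2 (153-fold higher, 95% interval 52.4 to 743) followed (adjusted p at most 0.0280). DM levels spread widely for Tnfrsf11b (17.0 ± 18.0 CPM), Il1rl1 (95.9 ± 87.4) and Postn (57.0 ± 75.9), whose folds hold for means. Tnfrsf11b, Postn and P2rx2 did not pass without EM clone 1 or EM clone 2. The largest falls were Cldn8 (-4.39 ± 0.38), the Wnt receptor Fzd10 (-4.80 ± 0.31), Lgi2 (-4.82 ± 0.30) and Sptssb (-5.66 ± 1.04; adjusted p at most 0.0145). The kallikreins Klk1b11 (-6.63 ± 0.97) and Klk1b9 (406-fold lower, 95% interval 72.9 to 16038) fell too (adjusted p at most 0.00866) and belong to a family of close copies, so each value is uncertain. Of 14282 tested genes 2247 changed, 1372 up and 875 down (3650 with the clone as a block, 2122 up and 1528 down), and 1191 of them by a log2 fold change of at least 1 in size. The count was 789, 1408, 1050 and 1956 without EM clone 1, DM clone 1, EM clone 2 and DM clone 2, ending 20, 10, 17 and 7 of the 42 named calls at adjusted p up to 0.210. With only the 4 libraries compared it was 924, ending 11.

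The medium effects in the uncloned and WT clone tables, which share no library, correlated across 12482 genes at Pearson's r of 0.811 and Spearman's rho of 0.687. Of the genes tested in both tables, the WT clones raised 1290 and lowered 837. Of these, 973 rose in both (230.4 for independent lists; 618 among genes of at least 10 CPM in both), 545 fell in both (116.7) and 5 moved in opposite directions. With labelled KO clones in place of WT, r was 0.723 and fewer genes passed, 677 raised and 470 lowered, of which 580 rose in both (120.9), 291 fell in both (65.5) and 6 moved in opposite directions.

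In the clones labelled Pax6-KO, DM was compared with EM to show the medium effect under that label. Part of the cell cycle genes, ion transport genes and Wnt targets fell, and part of the TGF-beta targets, contractile genes and fibroblast genes rose. Cell cycle genes fell for 16 of 30 and rose for none (0 up, 28 down by list; 25 fell with the clone as a block), at camera adjusted p = 4.76e-19 and adjusted p = 0.395 with an estimated correlation, and adjusted p = 0.105 with fry. Mcm2 (-1.46 ± 0.18), Hmgb2 (-1.60 ± 0.29), Cenpf (-2.54 ± 0.47) and Cdc20 (-2.13 ± 0.40) fell (adjusted p at most 0.0264). With any 1 of the 4 libraries left out, at most 2 cell cycle genes fell. Duct and ion transport genes fell for 5 of 18 and rose for none (1 up, 6 down by list; 3 rose and 7 fell with the clone as a block), at camera adjusted p = 0.0125 and adjusted p = 0.285 with an estimated correlation, and adjusted p = 0.0706 with fry. The sodium pump subunit Atp1b1 (-1.99 ± 0.30) and the sodium channel subunits Scnn1g (-4.93 ± 0.67) and Scnn1a (-1.80 ± 0.35) fell (n = 2 each, adjusted p at most 0.0271), and at most 1 duct gene fell with any 1 of the 4 left out. Wnt targets fell for 2 of 12 and rose for none (2 up, 8 down by list; 1 rose and 6 fell with the clone as a block), at camera adjusted p = 5.56e-05 and adjusted p = 0.0760 with an estimated correlation. Axin2 (-2.29 ± 0.12) and the receptor ligase Rnf43 (-1.22 ± 0.18) fell (adjusted p at most 0.0124), and Apcdd1 (-1.54 ± 0.42, adjusted p = 0.0701) and Notum (-2.45 ± 0.68, adjusted p = 0.0725) passed only with the clone as a block, DESeq2 or no filter. Rnf43 did not pass without DM clone 1, EM clone 2 or DM clone 2. BMP and TGF-beta targets rose for 5 of 13 (8 up, 0 down by list; 8 rose with the clone as a block), at camera adjusted p = 8.43e-09 and adjusted p = 0.0682 with an estimated correlation. Skil (1.33 ± 0.10), Pmepa1 (2.25 ± 0.26), Ccn2 (2.98 ± 0.41) and Tgfbi (2.48 ± 0.39) rose (adjusted p at most 0.0155). The rises in this list were 2, 1 and 3 without EM clone 1, EM clone 2 and DM clone 2. Myoepithelial genes rose for 3 of 8 (5 up, 0 down by list), at camera adjusted p = 2.73e-05 and adjusted p = 0.0760 with an estimated correlation. At most 1 rose without EM clone 1 or EM clone 2. Smtn (1.71 ± 0.18), Mylk (270.1-fold higher, 95% interval 48.5 to 10669) and Acta2 (5.28 ± 1.12) rose (adjusted p at most 0.0362), and the myosin light chain Myl9 stood at 0.104 ± 0.148 and 3.03 ± 2.03 CPM (adjusted p = 0.101). Fibroblast genes rose for 2 of 5, Fn1 (3.40 ± 0.44) and Col6a2 (2.84 ± 0.62; adjusted p at most 0.0464; 3 up, 1 down by list). The fibroblast list gave camera adjusted p = 0.00714 and adjusted p = 0.271 with an estimated correlation. Sparc (4.88 ± 1.23, adjusted p = 0.0567) did not pass, nor Col6a2 without any 1 of the 4 libraries. Acta1 rose as 1 of 6 fat and muscle genes (65.4-fold higher, 95% interval 18.1 to 540.1, adjusted p = 0.00736), at camera adjusted p = 0.414 and adjusted p = 0.931 with an estimated correlation, but did not pass without EM clone 1 or EM clone 2. Of 2 lymphocyte genes Pou2af1 fell (-3.09 ± 0.59, adjusted p = 0.0270), a call lost without any 1 of the 4. In labelled KO, mitochondrial transcripts held 1.22 and 1.17% of counts in EM and 1.10 and 0.921% in DM, and the rRNA-like transcript 1.20 and 0.853% against 1.22 and 1.62%.

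Under this label the largest rises were Postn (736-fold higher, 95% interval 204 to 6080.4), Csf2 (504-fold higher, 95% interval 90.5 to 19914), the arginine deiminase Padi2 (6.49 ± 0.77), Acsbg1 (6.38 ± 0.36), Lgr6 (5.85 ± 0.34) and Ggt5 (5.77 ± 0.50; adjusted p at most 0.0473). The largest falls besides Scnn1g were the antimicrobial lectin Reg3g (-4.11 ± 0.80), Kbtbd11 (-4.33 ± 0.54) and the kallikreins Klk1b27 (-4.63 ± 0.35) and Klk1b11 (-6.23 ± 0.96; adjusted p at most 0.0280). Sptssb fell as well (-3.97 ± 0.95, adjusted p = 0.0490), a call lost with DESeq2's size factors (adjusted p = 0.0503) and without any 1 of the 4 libraries (up to 0.193). Of 14282 tested genes 1193 changed, 706 up and 487 down (2338 with the clone as a block, 1321 up and 1017 down, and 1894 with DESeq2). The count was 170, 230, 82 and 284 without EM clone 1, DM clone 1, EM clone 2 and DM clone 2, ending 17, 17, 21 and 16 of the 32 named calls at adjusted p up to 0.244.

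Clones labelled Pax6-KO were compared with WT clones in EM to show what differed with the label during expansion. Interferon response genes were higher under the KO label for 21 of 23 and lower for 1 (22 up, 1 down by list), at camera adjusted p = 1.29e-48 and adjusted p = 0.282 with an estimated correlation. Ifit2 stood at 24.7 ± 2.94 CPM in WT and 369 ± 14.8 CPM in labelled KO (n = 2 each, 3.90 ± 0.28, adjusted p = 0.00273), and Rsad2 at 23.2 ± 6.78 and 382 ± 50.8 CPM (4.04 ± 0.31, adjusted p = 0.00273). Ddx58 was higher (1.86 ± 0.16, adjusted p = 0.00464), and Ifi27, an interferon-induced mitochondrial protein, was lower (-1.89 ± 0.13, adjusted p = 0.00273). Without labelled KO clone 1 and 2, 15 and 14 genes of the list passed as higher. The largest rises were the interferon-inducible genes Slfn1 (1152-fold higher, 95% interval 319 to 9513; ENSMUSG00000078763, chromosome 11, 83116849 to 83122670) and Ifi206 (6.95 ± 0.47) and the TGF-beta anchor Lrrc32 (5.90 ± 0.60). Palmd (5.74 ± 0.51), Calm4 (5.38 ± 0.88) and Skint3 (5.17 ± 0.40) followed (adjusted p at most 0.0156). Hypoxia and glycolysis genes were lower for 8 of 20 and higher for none (0 up, 13 down by list), at camera adjusted p = 1.75e-08 and adjusted p = 0.473 with an estimated correlation, and adjusted p = 0.0522 with fry. The collagen prolyl hydroxylase P4ha1 (-1.30 ± 0.14), Bnip3 (-0.94 ± 0.17), the angiogenic factor Vegfa (-1.39 ± 0.29) and Pgk1 (-0.73 ± 0.15) were lower (adjusted p at most 0.0311). Only 5 passed without WT clone 2, and 1 without any other of the 4 libraries. Cholesterol biosynthesis genes were lower for 3 of 24 and higher for none (0 up, 9 down by list), at camera adjusted p = 4.16e-07 and adjusted p = 0.875 with an estimated correlation, and adjusted p = 0.260 with fry. Insig1 (-2.96 ± 0.22) and Sc5d (-0.61 ± 0.12) were lower (adjusted p at most 0.0262), and Dhcr7 did not pass (-0.73 ± 0.20, adjusted p = 0.0681). Stard4 was lower (-1.06 ± 0.24, adjusted p = 0.0373). That call was lost with only the 4 libraries compared and without WT clone 1, WT clone 2 or labelled KO clone 1. In this list 6 passed without labelled KO clone 2, and 1 without any other of the 4. The p53 targets were lower for 7 of 20 and higher for none (2 up, 9 down by list), at camera adjusted p = 4.58e-05 and adjusted p = 0.334 with an estimated correlation. Btg2 (-1.27 ± 0.11), Sesn1 (-0.75 ± 0.12), Pmaip1 (-1.40 ± 0.24) and Zmat3 (-0.80 ± 0.15) were lower (adjusted p at most 0.0229). Of the p53 targets 2 passed without WT clone 1, and 1 without any other of the 4.

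Of other cell types, fibroblast genes were higher in EM for 2 of 5 (2 up, 1 down by list), Col6a1 (at least 47.0-fold higher) and Col6a2 (at least 7.45-fold higher; adjusted p at most 0.0300), at camera adjusted p = 0.495 and adjusted p = 0.875 with an estimated correlation. Of 5 macrophage genes Cd163 was higher, from 0.158 ± 0.0914 CPM in WT to 3.47 ± 0.841 CPM (4.39 ± 0.53, adjusted p = 0.00966; 1 up, 1 down by list), at camera adjusted p = 0.969 and adjusted p = 0.980 with an estimated correlation. Cd68, the most abundant of them, did not pass (-1.36 ± 0.37, adjusted p = 0.0649). Notch3 of 5 endothelial and pericyte genes (-0.9989 ± 0.2416, adjusted p = 0.0470; 1 up, 1 down by list) and Mbp of 5 nerve genes (-0.60 ± 0.12, adjusted p = 0.0306; 1 up, 1 down by list) were lower. The endothelial and nerve lists gave camera adjusted p = 0.896 and 0.991, and adjusted p = 0.922 and 0.995 with an estimated correlation. Cd163 did not pass without labelled KO clone 2, nor Col6a1 without any other of the 4 libraries or with only these 4 compared. Col6a2, Notch3 and Mbp did not pass without any 1 of the 4. Mitochondrial transcripts held 1.67 and 1.77% of counts in WT EM and 1.22 and 1.17% in labelled KO EM, and an rRNA-like transcript 1.94 and 1.74% against 1.20 and 0.853%.

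Among the largest falls, the neighbouring metalloproteases Adam28 (ENSMUSG00000014725, chromosome 14, 68606027 to 68655842) and Adamdec1 (ENSMUSG00000022057, chromosome 14, 68563380 to 68582095) were lower in labelled KO. Adam28 stood at 100.1 ± 3.56 CPM in WT and 0.960 ± 0.929 CPM in labelled KO (-6.71 ± 0.84, adjusted p = 0.00800), and Adamdec1 was at least 146-fold lower, adjusted p = 0.0127. A2ml1, a protease inhibitor, stood at 508 ± 452 and 0.710 ± 0.782 CPM (-9.46 ± 1.03, adjusted p = 0.00615; ENSMUSG00000047228, chromosome 6, 128539821 to 128581608). The sulfotransferase Chst9 (at least 158-fold lower), Thsd4 (178-fold lower, 95% interval 61.0 to 865) and the transcription factor Irf8 (-6.51 ± 0.85) completed them (adjusted p at most 0.0179). Of 14282 tested genes 1399 differed, 769 up and 630 down (996 down with DESeq2), and 2 named calls ended with only the 4 libraries compared. The count was 494, 409, 241 and 175 without WT clone 1, WT clone 2, labelled KO clone 1 and labelled KO clone 2, ending 12, 13, 18 and 16 of the 32 named calls at adjusted p up to 0.215. The fit treats the EM and DM libraries of a clone as independent although their deviations correlate at 0.60 (WT) and 0.51 (labelled KO), and all p-values measure only the spread between these samples, since the labels do not state separate animals or cultures.

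**Figure D3:**
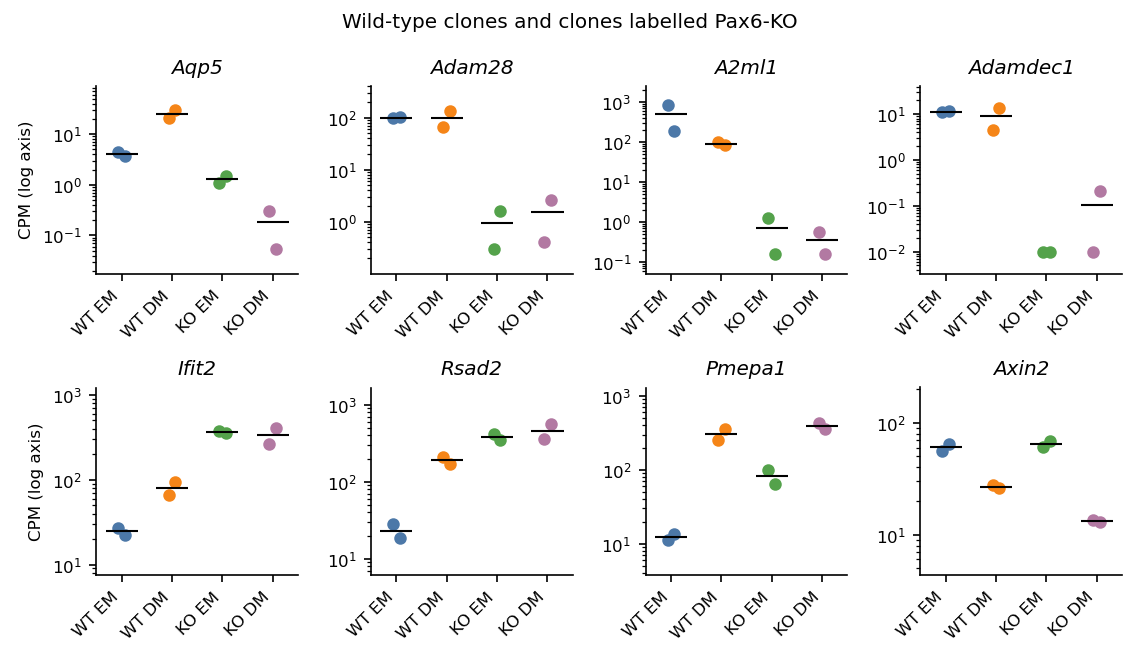
Level in CPM (y axis, log scale with its own range per gene) of 8 genes in WT clones and clones labelled Pax6-KO in EM and DM (x axis); points are libraries, lines are means, and libraries with no counts are drawn at 0.01 CPM. Adam28, A2ml1 and Adamdec1 are lower in labelled KO than in WT in both media, and Ifit2 and Rsad2 are lowest in WT EM. Aqp5 is higher in DM than in EM in WT and lower in labelled KO, where its means are 1.29 CPM in EM and 0.181 CPM in DM.

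Clones labelled Pax6-KO were compared with WT clones in DM to show what differed with the label there. Acinar secretory genes were lower under the KO label for 6 of 25 and higher for none (1 up, 8 down by list), at camera adjusted p = 1.22e-05 and adjusted p = 0.550 with an estimated correlation, and adjusted p = 0.0683 with fry. Aqp5 stood at 25.2 ± 6.18 CPM in WT and 0.181 ± 0.180 CPM in labelled KO (n = 2 each, -7.07 ± 0.58, adjusted p = 0.00734; ENSMUSG00000044217, chromosome 15, 99590782 to 99594829). The muscarinic receptor Chrm3 (at least 53.6-fold lower), the signal peptidase subunit Spcs3 (-0.73 ± 0.09) and the transcription factor Creb3l2 (-0.90 ± 0.12) were lower (adjusted p at most 0.0180). At most 3 acinar genes passed as lower without WT clone 1, labelled KO clone 1 or labelled KO clone 2, and 2 as higher without WT clone 2. Growth factor and MAPK targets were lower for 1 of 18, Areg (-1.41 ± 0.24, adjusted p = 0.0292; 0 up, 7 down by list), at camera adjusted p = 8.16e-05 and adjusted p = 0.550 with an estimated correlation, and adjusted p = 0.0747 with fry. Hbegf (-0.87 ± 0.20), Phlda1 (-0.87 ± 0.20) and Tgfa (-0.48 ± 0.12) did not pass. Areg did not pass without any 1 of the 4 libraries or with only these compared. Interferon response genes were higher for 5 of 23 and lower for 1 (17 up, 1 down by list), at camera adjusted p = 1.21e-10 and adjusted p = 0.632 with an estimated correlation, and adjusted p = 0.201 with fry. At most 2 passed as higher without any 1 of the 4. Hypoxia and glycolysis genes were lower for 2 of 20, P4ha1 (-1.63 ± 0.14) and Pfkp (-1.04 ± 0.17; adjusted p at most 0.0260; 0 up, 7 down by list), at camera adjusted p = 1.22e-05 and adjusted p = 0.550 with an estimated correlation, and adjusted p = 0.0843 with fry. Cholesterol biosynthesis genes were lower for 2 of 24, Insig1 (-2.44 ± 0.22) and Sc5d (-0.62 ± 0.12; adjusted p at most 0.0374; 0 up, 5 down by list), at camera adjusted p = 8.16e-05 and adjusted p = 0.822 with an estimated correlation, and adjusted p = 0.292 with fry. P4ha1 and Insig1 did not pass without labelled KO clone 1, Sc5d without any 1 of the 4 libraries or with only these compared, nor Pfkp with only these compared or without any 1 but WT clone 2 (adjusted p up to 0.194). Fibroblast genes were higher for 2 of 5, Col6a2 (4.11 ± 0.68) and Col6a1 (5.11 ± 1.03; adjusted p at most 0.0484), at camera adjusted p = 0.241 and adjusted p = 0.706 with an estimated correlation. Of 5 macrophage genes Cd163 was higher (at least 45.3-fold higher, adjusted p = 0.0132) and Cd68 lower (-2.15 ± 0.38, adjusted p = 0.0302), at camera adjusted p = 0.909 and adjusted p = 0.913 with an estimated correlation. Mbp of 5 nerve genes was lower (-0.80 ± 0.13, adjusted p = 0.0249; 2 up, 1 down by list), at camera adjusted p = 0.880 and adjusted p = 0.913 with an estimated correlation. Each of these 5 calls of fibroblast, macrophage and nerve genes was lost without labelled KO clone 1, and Cd163 alone passed without each of the other 3 libraries. Col6a2 and Mbp also did not pass with only the 4 libraries compared. The largest rises were Calm4 (6.99 ± 1.01), Fam83a (6.55 ± 0.97), Pi15 (6.07 ± 1.26), the complement protease C1ra (4.71 ± 0.75), Fam189a2 (4.44 ± 0.69) and Gphb5 (4.13 ± 0.72; adjusted p at most 0.0427). The largest falls besides Aqp5 were A2ml1 (-7.91 ± 1.07), Thsd4 (-6.85 ± 1.20), the keratin Krt20 (-6.53 ± 0.75), Smpdl3a (-6.46 ± 1.02) and Adam28 (-6.04 ± 0.79; adjusted p at most 0.0295). Of 14282 tested genes 781 differed, 341 up and 440 down (1556 with DESeq2, and 110 with only the 4 libraries compared, ending 13 of the 25 named calls). The count was 204, 524 and 127 without WT clone 1, WT clone 2 and labelled KO clone 2, ending 14, 9 and 18 of the named calls, and 275 of the 524 were lower. It was 0 without labelled KO clone 1 (edgeR, with 2373 at an unadjusted p under 0.05), ending all 25, and the ended calls had adjusted p up to 0.194.

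Whether the medium effect differed between labelled KO and WT was tested as an interaction. By edgeR 0 of 14282 genes passed (1126 at an unadjusted p under 0.05), while 70 passed with the clone as a block (6 up and 64 down) and 179 with DESeq2 (28 up and 151 down). Aqp5 rose in DM in WT (2.64 ± 0.42, adjusted p = 0.00970) and fell in labelled KO (-2.78 ± 0.58, adjusted p = 0.0351). The difference of -5.42 ± 0.71 passed with the clone as a block (-5.39 ± 0.71, adjusted p = 0.0373) and did not pass without it (adjusted p = 0.227). Interferon response genes rose in DM for 18 of 23 in WT and for 0 in labelled KO by edgeR without a block. In labelled KO 2 of them passed an unadjusted p under 0.05, Ifi44 (0.68 ± 0.18) and Ifi27 (-0.55 ± 0.13). With the clone as a block 22 rose and 1 fell in WT, and 1 rose and 2 fell in labelled KO. The list gave camera adjusted p = 0.794 and adjusted p = 0.958 with an estimated correlation in labelled KO, and its difference between the labels gave camera adjusted p = 1.31e-39 and adjusted p = 0.227 with an estimated correlation, and adjusted p = 0.148 with fry.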

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

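The splits of the samples and the tests of explanations for the interferon genes were chosen after the results were seen, and the interaction tests were planned. Naming interaction genes from the fit with the clone as a block was also chosen after the result was seen. The medium effect differed between labelled KO and WT for 70 genes with the clone as a block. Those named by the rule with a difference above 0 were Fmo2 (2.45 ± 0.35), Vgll3 (2.17 ± 0.29), Pdzrn3 (1.98 ± 0.25), Gstm1 (1.73 ± 0.20), Pdlim2 (1.72 ± 0.18) and Serpine2 (1.44 ± 0.15). Those below 0 were Skint3 (-3.31 ± 0.41), Clca3b (-3.51 ± 0.44), Ifi205 (-3.85 ± 0.35), and Aqp5 (-5.39 ± 0.71), and also Slfn1 and Rgs4. The fitted values of Slfn1 (-6.36) and Rgs4 (-7.28) rest on 2 and 0 counts in WT EM and depend on the prior count, so they give a direction and no size. All 12 passed with the clone as a block, at adjusted p from 0.0186 to 0.0440, and by edgeR none of the 14282 genes tested passed without it (1126 at an unadjusted p under 0.05, and 179 passed with DESeq2).

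The interaction also passed camera with its preset correlation for 10 gene lists. The adjusted p was 1.31e-39 for interferon response, 4.51e-05 for cell cycle, 1.78e-04 for p53 targets, 2.85e-04 for acinar secretory machinery and 2.85e-04 for BMP and TGF-beta targets. It was 0.00146 for the unfolded protein response, 0.0158 for growth factor and MAPK targets, 0.0233 for keratinization, 0.0494 for myoepithelial cells and 0.0494 for hypoxia and glycolysis. The p53, myoepithelial and hypoxia lists moved up in labelled KO relative to WT, and the other 7 moved down. None of the 10 passed with fry (adjusted p from 0.148 to 0.643) or with an estimated correlation, with the lowest of the latter, adjusted p = 0.227 with an estimated correlation, for interferon response and for BMP and TGF-beta targets.

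Interferon response genes stood higher in labelled KO than in WT clones in EM. A single deviating culture is argued against by 22 of 23 genes with both labelled KO libraries above both WT libraries. Immune cells are argued against by a median of 0.0379 CPM in labelled KO EM over the 12 macrophage genes of at least 10 CPM in the gland, a level scaled apart from that of the gland, where the most abundant, H2-Aa and Cd74, stood at 145 and 143 CPM against 0 and 1.05 CPM, with Cd68 the exception at 48.4 CPM (124.5 CPM in WT) and with Cd163, below 10 CPM in the gland and so not among the 12, higher at 3.47 CPM (0.158 CPM in WT). That test replaced an earlier one that decided nothing, a median change of -0.34 over 5 tested genes that went both ways. Differences between clones unrelated to Pax6 may be the source and stay open, since 1 of 3 splits of the 4 EM libraries, the real one, gave as large a gap (2.47, highest other 0.435), 3 splits are too few for a share under 0.05, and with these clones this cannot be told apart from an effect of the labelled knockout.

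For the calls in uncloned organoids and tissue, 3 against 3 libraries make 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many calls in DM against EM (4158, highest other 1). The same held for EM against tissue (1 of 10, 10259, highest other 0) and for DM against tissue (1 of 10, 10358, highest other 0).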

How the results depend on the processing

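Total-count scaling was chosen after seeing the data and the other alternatives were planned. Of 3851 values for named genes under alternatives, 3437 kept direction and side of the threshold, 115 came to pass, 297 ceased to pass (267 of them with 1 library left out) and 2 reversed. The 2 reversed were Pax6 against tissue, at 1.26 in EM and 1.21 in DM with total-count scaling, which by construction has no composition factor and moved the median of all genes by 2.06 and 1.97 there and by under 0.1 elsewhere. Of 585 values for gene lists, 483 stayed, 21 came to pass and 81 ceased to pass, and the number of lists past camera fell from 76 to 19 with an estimated correlation. The cause was not tested for any of the following unless named. Without a low-count filter 3497 were called in WT DM against EM, 2572 in KO DM against EM, 2947 in KO against WT in EM, 2547 in KO against WT in DM and 657 in the interaction. DESeq2 called 1894 in KO DM against EM, 1556 in KO against WT in DM and 179 in the interaction. With the clone as a replicate block, 3650 were called in WT DM against EM, 2338 in KO DM against EM and 70 in the interaction. WT and KO clones share only a number, and a block on it gave 1740 calls in EM and 1099 in DM. The block ended the camera calls of retinoid genes (adjusted p = 0.223) and fibroblast genes (0.272) in uncloned DM against EM, ended among named genes only Cd163 in WT DM against EM (0.0608) and no other list, and brought 27 gene and 4 list values past the threshold. Using only the 4 libraries compared, 924 were called in WT DM against EM and 110 in KO against WT in DM. With 1 library left out, the lone library of its group is assumed to vary like the other groups. The calls then ranged from 789 to 1956 in WT DM against EM, from 82 to 284 in KO DM against EM, and from 175 to 494 in KO against WT in EM. They ranged from 0 to 524 in KO against WT in DM (the 0 by edgeR without labelled KO DM clone 1, with 2373 at an unadjusted p under 0.05) and from 0 to 14 in the interaction (14 without WT DM clone 2). The difference in similarity to tissue was -0.0320 with Pearson's r and -0.0396 over genes of at least 10 CPM, against -0.0245. With labelled KO in place of WT clones, 871 genes moved alike with the uncloned organoids, against 1518, of 677 raised and 470 lowered against 1290 and 837. The share of genes moved toward tissue was 61.2% with total-count scaling, against 54.3%. Every other total for a comparison, 71 of 104 values, stayed within 1.5 times, though its rises or falls alone could move further (falls in uncloned DM against EM from 1039 to 2581 with 1 library left out), or for similarity and the share toward tissue within the spread. At these depths and sample numbers, 2-fold changes in the clones were recovered less often than in the uncloned organoids on simulated counts.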

Other observations

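The list counts below were planned, and all tests of line 8 and of the labelled KO clones in EM, and the look at neighbours of Adam28, were chosen after the result was seen. Genes of the Notch pathway were higher in EM than in the gland for 10 of 13 and lower for 2 (12 and 0 with total-count scaling). The Notch list gave camera adjusted p = 5.80e-04 and adjusted p = 0.0536 with an estimated correlation. Transcription regulators of lacrimal gland and eye split into 12 higher and 8 lower of 24 (22 and 2 with total-count scaling). That list gave camera adjusted p = 0.418 and adjusted p = 0.736 with an estimated correlation. DM lowered 9 of these 24 and raised 3 (3 up, 11 down by list), but lowered 5 without EM of line 8 and 4 without DM of line 6. This gave camera adjusted p = 0.126 and adjusted p = 0.775 with an estimated correlation. Corneal and conjunctival genes were higher for 6 of 9 and lower for 2. That list gave camera adjusted p = 0.141 and adjusted p = 0.235 with an estimated correlation. Stress and unfolded protein response genes were higher for 11 of 20 and lower for 6 (16 and 2 with total-count scaling). That list did not pass camera (adjusted p = 0.1302, and adjusted p = 0.419 with an estimated correlation) and passed fry (adjusted p = 3.82e-04).

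Lymphocyte genes fell from gland to EM for 5 of 6 and rose for 1, a rise that did not pass without gland 6 or EM of line 7. The list did not pass camera (adjusted p = 0.0963, and adjusted p = 0.20002 with an estimated correlation). Nerve genes, and also fat and muscle genes, split into 2 up and 2 down of 6 (4 up and 2 down with total-count scaling). These 2 lists gave camera adjusted p = 0.418 and 0.773, and adjusted p = 0.486 and 0.778 with an estimated correlation. For salivary gland, 3 genes were tested, too few for camera, with 1 up and 1 down, the fall not passing without gland 8 or any 1 EM library. These lists of regulators, corneal, lymphocyte, nerve and fat and muscle genes passed fry in EM against the gland (adjusted p at most 0.0145). Of the sex-linked transcripts Xist was the 1 tested, at 480.2 ± 37.2 CPM in the gland and 869.8 ± 80.9 CPM in EM (0.86 ± 0.10, adjusted p = 1.23e-05).

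In uncloned DM, line 8 lay nearer to EM than lines 6 and 7. Held out of the fit, it stood 0.541 of the way from EM to DM for 1192 genes that the other lines raised (quartiles 0.344 to 0.779) and 0.672 for 700 that they lowered (0.311 to 0.873), while lines 6 and 7 held out alike stood at 1.08 and 1.30 for raised genes. The 28 cell cycle genes lower in DM at an unadjusted p under 0.05 without line 8 stood at -0.0887 (EM libraries -0.0756 to 0.132), and this difference of 0.630 from the raised genes argues against a mixture with EM material as the whole source, since all sets would share a position. A swap with the EM library of line 8 is argued against by that library's position, 0.000800 of the way from the other EM libraries to DM of lines 6 and 7 over the raised genes. For the raised and lowered genes, which differ by -0.131, such a mixture stays open, and no biological explanation was tested.

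Clones labelled Pax6-KO in EM lay part of the way along the change that DM gives, and for the genes that DM lowered the median was below 0 in DM too. The 956 genes that DM raised by a log2 fold change of at least 1 in uncloned organoids had a median difference of labelled KO from WT of 0.41 in EM (167 higher and 38 lower past the test, 63.7% above 0, unadjusted camera p = 0.00226 with an estimated correlation) and -0.03 in DM (p = 0.863). The 368 that DM lowered by as much had -0.35 in EM (10 higher and 47 lower past the test, unadjusted camera p = 0.00876 with an estimated correlation) and -0.23 in DM (19 higher and 34 lower, p = 0.0855, and 0.0125 with fry). Whether a wider interferon response may be the source stays open, since the list holds only 1 of these genes and leaving it out (a median of 0.414 over 955) tests nothing. Differences between clones unrelated to Pax6 may be the source and stay open, since 1 of 3 splits of the 4 EM libraries gave a gap as large (0.474, highest other 0.101), 3 splits are too few for a share under 0.05, and an effect of the labelled knockout stays open too.

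Of 7 tested genes within 1 Mb of Adam28 on chromosome 14, Adam28, Adamdec1 and Slc25a37 (-1.39 ± 0.20, adjusted p = 0.0112) were lower in labelled KO than in WT in EM. The others, Dock5 (-0.29 ± 0.36), Kctd9 (-0.28 ± 0.16), Cdca2 (0.39 ± 0.49) and AC093020.1 (0.72 ± 1.07), did not pass. In DM, Adam28 and Adamdec1 passed (adjusted p at most 0.0302), and Slc25a37 (-0.87 ± 0.20, adjusted p = 0.0549), Dock5 (-1.05 ± 0.36, adjusted p = 0.133), Kctd9 (-0.22 ± 0.16), Cdca2 (-0.39 ± 0.52) and AC093020.1 (0.10 ± 1.53) did not.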
